A study of Arabidopsis thaliana with 30 samples.

How the data were processed

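Messenger RNA was measured by sequencing in 30 libraries of Arabidopsis thaliana, a small flowering plant used as a laboratory model. The libraries came from wild-type seedlings (accession Columbia, called Col) and from the mutant ahp4, named in the series' design text as the allele ahp4-2. AHP4 is 1 of the 6 histidine phosphotransfer proteins (AHPs) of this species. This family passes phosphate from the cytokinin receptors in the membrane to response regulators in the nucleus, except AHP6, which inhibits the signalling. Seedlings 7 days old were parted at the hypocotyl into root and shoot pools. They were kept for 2 h in liquid medium with 100 nM 6-benzylaminopurine (BA), a synthetic cytokinin, or with 0.1% DMSO alone, the mock treatment, and the labels leave open whether this was before or after they were parted. Genotype, tissue and treatment gave 8 groups of 4 libraries each, except the mock and BA groups of ahp4 shoots, which had 3 each. Per the labels' protocols, polyadenylated RNA was copied from random hexamers and sequenced as paired 150 bp reads. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

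The deposited table gives FPKM values, fragments scaled by gene length and library depth, for 33199 features. The genome build was TAIR10, per the submitters' processing notes. The aligner, the counting tool and the use of strand are not given in the sources used here, so genes that overlap another gene are reported as uncertain. Of the features, 32833 had a gene code and 366 were unannotated models numbered by the authors, and 6306 were listed at 0 in each library. Gene names were taken from the TAIR10.1 annotation for the 32548 codes that matched it. This annotation was used only for names, for overlaps and for which genes neighbour each other.

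The FPKM values of each feature were whole multiples of a common step, so whole reads could be rebuilt for 100% of the features, within a tolerance of 0.01 reads. Rebuilt totals ran from 9205127 to 13779004 reads per library. The scale of the deposited FPKM values equalled median-of-ratios size factors over the 30 libraries, computed from the 17484 features above 0 in each library, with a largest relative deviation of 1.3e-15. It was not a scale of read totals. On this scale shoots held 1.402 times as many reads per size factor as roots, so a level compared between tissues depends on the scaling. Between replicates of a group the chi-square of the rebuilt reads per degree of freedom ran from 3.008 to 21.913, and no pair of libraries looked like repeats of 1 library. At these depths a value under 1 FPKM often rested on fewer than 10 rebuilt reads, as the values of AHP4 show.

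Groups were taken from the sample titles. For ahp4 root mock replicate 1, the title and description said ahp4 and mock while the characteristics said Col-0 and BA. It was grouped by its title. Comparisons that use its group were also computed without it, as were their list tests within roots. The BA response of Col roots and ahp4 against Col in BA roots, whose fit it shares, were not. The split tests and the tests chosen after the results were seen were not repeated without it either.

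The main test was limma 3.58.1 (linear models with a mean-variance trend) in R 4.3.3, on log2(FPKM + 1). Genes with an FPKM of 1 or more in at least 3 libraries of the fit were tested, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 4 groups of a tissue shared 1 fit with no replicate block. Comparisons between tissues used all 8 groups and took root and shoot libraries as independent, though they may come from the same seedlings. A fold change is on the log2(FPKM + 1) scale throughout, which understates the change of low genes. Errors of group levels are SD over libraries, and errors of log2 changes are standard errors. The AHP4 level was compared by a two-sided exact permutation test on log2(FPKM + 1), computed in R. Figures were drawn with matplotlib 3.10.9, and tables were read with python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The test was checked on simulated data in which 200 genes had been changed by known amounts.

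The tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named, in each comparison within a tissue, the 10 genes with the highest and the 10 with the lowest log2 change among called genes that had a symbol, a mean FPKM of 1 or more in the higher group and no overlap between the libraries of both groups. It also named the 6 AHP genes, the 10 type-A response regulators and up to 4 called members of each list, or the member with the smallest p where none was called. For an interaction or a difference between tissues, overlap was not considered. The 24 lists held 263 genes, each found in the table. They were type-A response regulators, type-B response regulators, AHPs, cytokinin receptors, cytokinin breakdown and conjugation, cytokinin synthesis, other textbook cytokinin-induced genes, auxin, ethylene, jasmonate and wounding, salicylate defence, abscisic acid and drought, touch and early stress, low oxygen, heat shock, circadian clock, nutrient uptake, iron deficiency, secondary wall and xylem, cell cycle, stomatal lineage, shoot markers, root markers and reference genes. Lists with at least 3 tested members were tested with camera, limma's competitive test of a gene list, at its preset correlation of 0.01 and again with an estimated correlation. Calls were adjusted over all genes tested and, separately, adjusted over the list alone.

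The alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, array weights, the replicate number as a block, 1 fit of all 8 groups, a fit of the compared groups only, and leaving out each library in turn. Limma voom on the rebuilt reads with the deposited scale, scaling by rebuilt read totals, the mean of the shoot markers as a covariate in roots, a term for 3 BA shoot libraries that stood apart (ahp4 replicates 2 and 3 and Col replicate 4), and another scaling of the AHP levels were added after seeing the data. A planned form of voom that needed gene lengths was replaced by this one, because the table gives no gene length. No library was left out of the main results.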

Results

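Transcript levels were compared between ahp4 and Col seedlings in roots and in shoots, with and without 2 h of BA. The series was set up to profile transcription in the mutant against the wild type in each organ. There were 4 libraries in each of the 4 root groups and of the 2 Col shoot groups, and 3 in each of the 2 ahp4 shoot groups. Rebuilt totals ran from 9205127 to 13779004 reads per library.

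The mean AHP4 level was lower in ahp4 than in Col in each organ and treatment, by an exact test in mock roots and BA shoots and not in BA roots or mock shoots. In mock roots the Col libraries had 1.71, 0.539, 0.901 and 0.879 FPKM. The ahp4 libraries had 0.350, 0.435, 0.347 and 0.381 FPKM. In BA roots the Col values were 0.538, 0.885, 0.0917 and 0 FPKM, and the ahp4 values were 0.514 FPKM in replicate 1 and 0 in the other 3. In mock shoots Col had 10.6, 2.66, 4.37 and 3.48 FPKM, and ahp4 had 2.49, 1.23 and 0.808 FPKM. In BA shoots Col had 1.88, 1.61, 3.71 and 1.72 FPKM, and ahp4 had 0.363, 0.614 and 0.622 FPKM. The ratio of the ahp4 mean to the Col mean was 0.376 in mock roots (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give), and 0.339 in BA roots (exact permutation p = 0.257). In shoots it was 0.287 under mock (exact permutation p = 0.0571) and 0.239 under BA (exact permutation p = 0.0286, the smallest for 3 against 4 libraries). These means rest on 17 against 53 and 6 against 19 rebuilt reads in roots, and on 47 against 174 and 13 against 72 in shoots. Without any 1 of the ahp4 libraries the exact permutation p in mock roots was 0.0571.

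**Figure D1:**
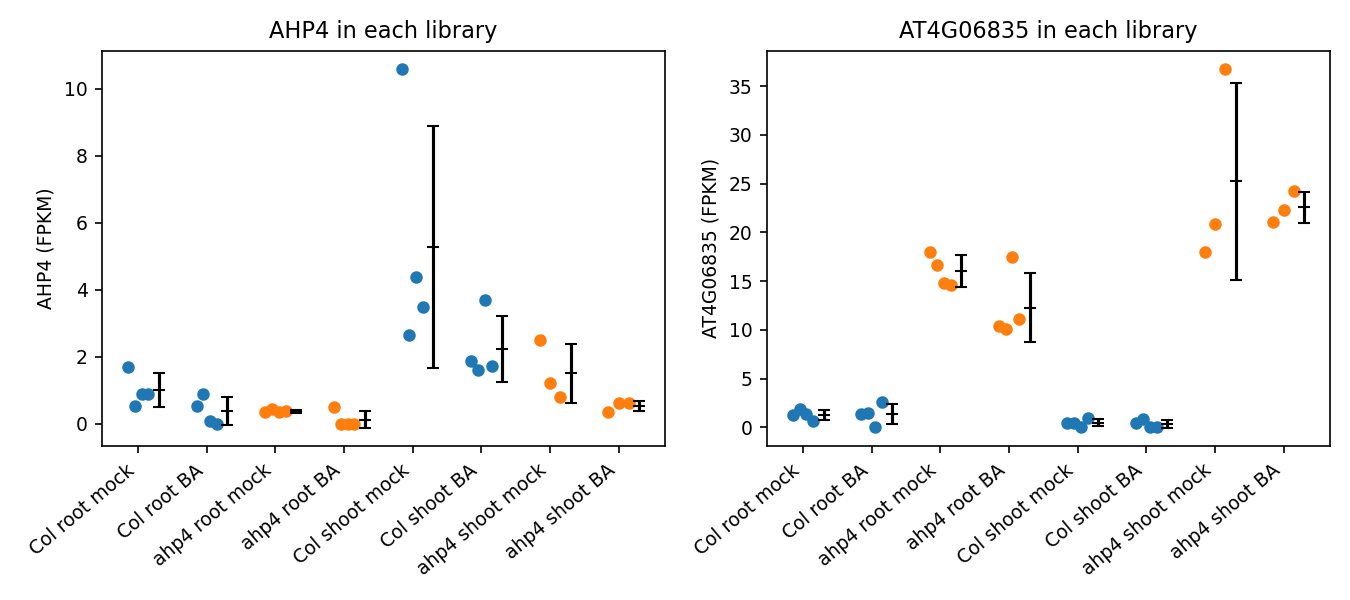
FPKM of AHP4 (left) and of the long noncoding RNA AT4G06835 (right) in each of the 30 libraries, by group. Blue points are Col and orange points ahp4 libraries, black bars are mean ± SD; AT4G06835 lay at 10.1 FPKM or more in each ahp4 library and at 2.57 FPKM or less in each Col library.

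The 6 AHP genes were spread unequally over the organs of mock-treated Col seedlings (n = 4 each). AHP1 was higher in roots by 4.55 ± 0.16 on the log2 scale (85.8 ± 10 FPKM in roots and 2.78 ± 0.903 in shoots), and AHP6, a pseudo-phosphotransfer protein that inhibits cytokinin signalling, by 1.55 ± 0.18 (3.02 with a pseudocount of 0.1). AHP3 was higher in roots by 0.71 ± 0.10. AHP4 was the member with its higher level in shoots, with a root minus shoot difference of -1.52 ± 0.27 (limma adjusted p = 1.14e-05 over the family). AHP2 (0.02 ± 0.11, adjusted p = 0.842) and AHP5 (-0.12 ± 0.11, adjusted p = 0.316) did not pass the test, but with scaling by read totals AHP2 became higher in roots by 0.56 and AHP5 turned to 0.39 higher in roots, and with quantile normalization AHP2 was higher by 0.21.

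In Col roots BA raised the type-A response regulators, the early targets and negative feedback regulators of cytokinin signalling. ARR5 rose 6.49-fold, from 25.0 ± 8.88 to 159 ± 14.8 FPKM (SD, n = 4), ARR7 rose 5.73-fold, ARR15 6.72-fold and ARR16 6.96-fold. On the log2(FPKM + 1) scale YLS9, a member of the NDR1/HIN1-like family, rose the most of the named genes, 9.04-fold, from 7.18 ± 3.34 to 68.8 ± 9.36 FPKM. By the ratio of group means low genes such as ARR15 (0.413 ± 0.242 to 8.44 ± 1.25 FPKM) rose more. The sulfotransferase gene ST4B rose 7.42-fold and GH3.3, whose enzyme conjugates auxin to amino acids, 6.74-fold. MYB28, a regulator of aliphatic glucosinolate synthesis, fell from 14.7 ± 3.6 to 2.32 ± 0.459 FPKM, and the terpene synthase gene TPS13 from 12.3 ± 4.01 to 1.11 ± 0.579 FPKM. Of 19418 genes tested by limma, 3982 were called, 2282 higher and 1700 lower, and 688 of them by a log2 change of 1 or more. The excess of higher genes depended on the scaling, with 2112 higher and 2218 lower with quantile normalization and 2116 and 2013 with read totals.

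The cytokinin genes were then taken by list. All 10 type-A response regulators rose, also when adjusted over the list alone (10), by a median log2 change of 1.81 (camera adjusted p = 1.48e-13, and adjusted p = 0.0349 with an estimated correlation). In the breakdown and conjugation list 7 of 9 rose (7 adjusted over the list alone), led by the cytokinin oxidase genes CKX3 (log2 1.78 ± 0.25), CKX5 (1.39 ± 0.13) and CKX4 (1.25 ± 0.16), with a camera adjusted p = 1.2e-05 and an adjusted p = 0.0349 with an estimated correlation. In the synthesis list 4 of 12 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.00461, adjusted p = 0.0349 with an estimated correlation). The isopentenyltransferase genes IPT5 and IPT3 fell by 2.19 and 2.04 and LOG1, whose enzyme releases active cytokinin, fell by 1.44, while CYP735A2, which encodes a cytokinin trans-hydroxylase, rose by 2.24 ± 0.15 to 50.7 ± 5.32 FPKM. Of the other textbook cytokinin-induced genes 7 of 11 rose (7 up and 1 down adjusted over the list alone), among them LBD3 (2.27 ± 0.22) and IAA3 (1.98 ± 0.19; camera adjusted p = 0.00284, adjusted p = 0.0349 with an estimated correlation). Among the 3 receptors AHK4 rose by 0.84 ± 0.10 and AHK3 by 0.46 ± 0.16, and AHK2 fell by 0.60 (2 up and 1 down adjusted over the list alone). The AHK3 call ended without mock replicate 3 or 4 or BA replicate 1, 2 or 4 (highest adjusted p = 0.144) and under 5 other alternatives. Of the type-B response regulators, the transcription factors of the pathway, ARR12 (0.60 ± 0.09) and ARR10 (0.35 ± 0.11) rose of 5 tested, and of 5 AHP genes AHP1 rose (0.48 ± 0.11). Adjusted over the list alone these counts were 2 and 2, and the ARR10 call ended without mock replicate 1, 2 or 4 or BA replicate 1 or 2 (highest adjusted p = 0.108) and under 3 other alternatives.

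Genes of other hormones changed as well. Of 23 auxin genes 10 rose and 3 fell (11 and 3 adjusted over the list alone), with GH3.3, IAA5 (log2 1.80 ± 0.18) and IAA17 (1.39 ± 0.09) among those that rose. The auxin list had a camera adjusted p = 0.00694 and an adjusted p = 0.131 with an estimated correlation, and its median was 0.02 while its mean was 0.43. In the abscisic acid and drought list 7 of 10 rose (8 adjusted over the list alone), including the NAC factor gene RD26 (1.85 ± 0.16) and NCED3 (1.23 ± 0.19), which encodes a key enzyme of abscisic acid synthesis, with a camera adjusted p = 1.2e-05 and an adjusted p = 0.131 with an estimated correlation. Of 14 ethylene genes 4 rose and 5 fell (4 and 6 adjusted over the list alone). The synthase gene ACS7 rose by 2.29 ± 0.21, while ACO1, for the last step of ethylene synthesis, fell by 1.45 and the receptor gene ETR2 fell by 1.27. The ethylene median was 0.11 and its mean -0.02, with a test direction of down (camera adjusted p = 0.679). Of 4 salicylate genes 3 rose (3 up and 1 down adjusted over the list alone), with WRKY70 at 1.53 ± 0.25 (camera adjusted p = 0.0508). None of 9 jasmonate genes was called by limma, over all genes or adjusted over the list alone (0), with a median of 0.06 and a test direction of down (camera adjusted p = 0.98).

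Single genes of uptake, metabolism and stress were called as well, in lists that did not pass with an estimated correlation. In the nutrient uptake list 3 of 10 fell (7 adjusted over the list alone), with the nitrate transporter genes NRT2.1 falling from 22.5 ± 8.08 to 7.56 ± 2.94 FPKM and NRT1.1 from 141 ± 35.3 to 61.5 ± 6.19 FPKM (camera adjusted p = 0.00343, adjusted p = 0.342 with an estimated correlation). FIT, the regulator of iron uptake, fell by 1.59 and bHLH39 by 0.96, of 6 iron deficiency genes (2 adjusted over the list alone; camera adjusted p = 0.34). In the low oxygen list HRE1 fell by 1.74 and SUS4 by 1.79, of 9 (3 adjusted over the list alone; camera adjusted p = 0.0153, adjusted p = 0.459 with an estimated correlation). The SUS4 call ended without mock replicate 3 or BA replicate 1 or 3 (highest adjusted p = 0.0615). In the secondary wall list 5 of 18 rose (10 adjusted over the list alone), among them KNAT7 (0.72 ± 0.14), with a camera adjusted p = 0.00414 and an adjusted p = 0.342 with an estimated correlation. In the cell cycle list 2 of 12 fell (8 adjusted over the list alone; camera adjusted p = 0.00694, adjusted p = 0.342 with an estimated correlation), both by under 0.5 on the log2 scale. These calls, of CDKB2;2 and KNOLLE, ended in 1 fit of all 8 groups (limma adjusted p = 0.164 and 0.251). They also ended with the shoot marker covariate (limma adjusted p = 0.0692 and 0.0694). Of 11 clock genes ELF3 rose (0.47 ± 0.09; 1 adjusted over the list alone; camera adjusted p = 0.039, adjusted p = 0.131 with an estimated correlation). In the touch list 2 of 8 rose (2 up and 2 down adjusted over the list alone), among them TCH4, with a median of -0.22, a mean of -0.07 and a test direction of up (camera adjusted p = 0.98), and in the heat shock list 2 of 4 rose (2 adjusted over the list alone), among them HSP90.1 (camera adjusted p = 0.113). The 4 reference genes had a median log2 change of 0.02 and none was called.

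Markers of the other organ were measured beside these groups. Of 12 shoot markers HEMA1, for the first step of chlorophyll precursor synthesis, rose from 26.7 ± 3.20 to 47.6 ± 5.28 FPKM, LHCB2.1, a light-harvesting protein gene, rose from 5.82 ± 5.13 to 18.9 ± 7.58 FPKM, and GLK2 fell by 0.43 (2 up and 1 down adjusted over the list alone; camera adjusted p = 0.185). The LHCB2.1 call ended without mock replicate 3 or 4 or BA replicate 2 (highest adjusted p = 0.087), and the GLK2 call without any library but mock replicate 4 (highest adjusted p = 0.157) and under 5 other alternatives. Across root libraries LHCB1.3 ranged from 14.8 to 120 FPKM and RBCS1A from 11 to 126 FPKM, against at least 15100 and 14300 FPKM in shoots. Of 14 root markers the triterpene synthase genes THAS (1.43 ± 0.20) and MRN1 (1.32 ± 0.27) rose (2 adjusted over the list alone), and no member of the stomatal lineage list passed the filter in roots.

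**Figure D2:**
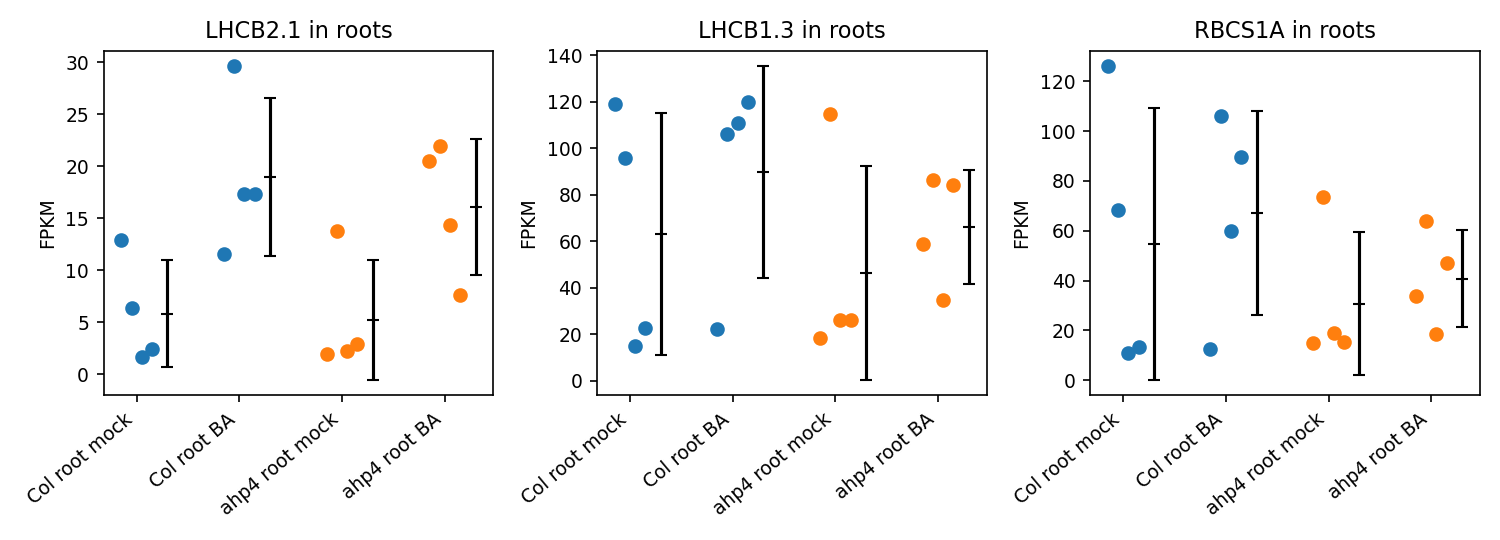
FPKM of 3 abundant leaf transcripts, LHCB2.1, LHCB1.3 and RBCS1A, in the 16 root libraries by group. Blue points are Col and orange points ahp4 libraries, and black bars are mean ± SD (n = 4); LHCB1.3 ranged from 14.8 to 120 FPKM within the roots.

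In ahp4 roots BA also changed cytokinin genes. ARR5 rose 7.12-fold, from 25.4 ± 9.96 to 177 ± 17.6 FPKM (SD, n = 4), YLS9 rose 9.18-fold, GH3.3 rose 6.13-fold and UGT74E2, a glucosyltransferase gene acting on an auxin precursor, 6.69-fold. The late embryogenesis genes LEA7 and LEA4-5, linked to drying, rose 5.85-fold and 5.50-fold. UMAMIT17, of an amino acid transporter family, fell from 44.5 ± 9.24 to 7.43 ± 1.74 FPKM, MYB28 fell by 2.27 on the log2 scale and the peroxidase gene Prx37 fell by 2.06. Of 19418 genes tested by limma 4020 were called, 2221 higher and 1799 lower, and 716 by a log2 change of 1 or more. With quantile normalization 2088 were higher and 2102 lower, and with read totals 2078 and 1984.

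All 10 type-A genes rose in ahp4 roots (10 adjusted over the list alone; median 1.82, camera adjusted p = 3.8e-13, adjusted p = 0.0538 with an estimated correlation), as did 7 of 9 breakdown genes (7 adjusted over the list alone; camera adjusted p = 7.49e-06, adjusted p = 0.0538 with an estimated correlation). In the synthesis list 4 of 12 fell and 1 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.121), with IPT5 falling by 2.06 and CYP735A2 rising by 2.44 ± 0.15. Of the other textbook genes 5 of 11 rose (6 adjusted over the list alone), LBD3 by 2.38 ± 0.22, with a camera adjusted p = 0.00616 and an adjusted p = 0.0538 with an estimated correlation. In the abscisic acid list 6 of 10 rose (7 adjusted over the list alone; camera adjusted p = 4.96e-05, adjusted p = 0.21 with an estimated correlation), with RD26 at 1.77 ± 0.16 and RD29A at 1.38 ± 0.25. In the nutrient uptake list 6 of 10 fell (8 adjusted over the list alone; camera adjusted p = 0.000245, adjusted p = 0.251 with an estimated correlation), NRT1.1 by 1.60 and NRT2.1 by 1.38. The auxin list had 8 up and 3 down of 23 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0193, adjusted p = 0.21 with an estimated correlation), the secondary wall list 6 up of 18 (6 adjusted over the list alone; camera adjusted p = 0.0144, adjusted p = 0.441 with an estimated correlation) and the cell cycle list 4 down of 12 (4 adjusted over the list alone; camera adjusted p = 0.0199, adjusted p = 0.441 with an estimated correlation). Among shoot markers HEMA1 (0.73 ± 0.11) and LHCB2.1 (1.72 ± 0.53) rose and GLK2 fell by 0.65, of 12. The LHCB2.1 call ended without mock replicate 1, 3 or 4 or BA replicate 1, 2 or 3 (highest adjusted p = 0.0871) and with no filter (adjusted p = 0.0509).

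In Col shoots the type-A response regulators led the response to BA. ARR15 rose 18.0-fold, from 0.406 ± 0.332 to 24.6 ± 7.16 FPKM (SD, n = 4), ARR5 rose 6.74-fold, ARR7 6.55-fold and ARR4 4.24-fold. CKX4 rose 3.15-fold, UGT76C2, which encodes a cytokinin N-glucosyltransferase, 2.65-fold, and the cytokinin response factor gene CRF2 2.71-fold. The microRNA gene MIR864 was listed at 0 in each mock library and had 3.41 ± 2.16 FPKM with BA. XTH15, of the enzymes that remodel xyloglucan in cell walls, fell from 6.88 ± 2.25 to 1.32 ± 0.718 FPKM, the metal transporter gene YSL3 fell from 51.2 ± 14.3 to 23.2 ± 3.66 FPKM and the sucrose exporter gene SWEET12 from 62.6 ± 12.1 to 30.4 ± 11 FPKM. Of 18246 genes tested by limma 1487 were called, 959 higher and 528 lower, and 174 by a log2 change of 1 or more.

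All 8 type-A genes tested in Col shoots rose (8 adjusted over the list alone; median 2.18, camera adjusted p = 1.34e-17, adjusted p = 0.0173 with an estimated correlation). In the breakdown list 4 of 6 rose (4 adjusted over the list alone; camera adjusted p = 5.07e-05) and of the other textbook genes 9 of 13 (10 adjusted over the list alone; camera adjusted p = 1.16e-08), each with an adjusted p = 0.0173 with an estimated correlation. AHK4 rose by 1.24 ± 0.12, of 3 receptors, and AHP1 by 0.94 ± 0.20, of 5 AHP genes. The ethylene receptor gene ERS1 fell by 0.44, of 12 ethylene genes (1 adjusted over the list alone; camera adjusted p = 0.075), the salicylate transporter gene EDS5 rose by 1.04 ± 0.18, of 5 (1 adjusted over the list alone), and the shoot marker GLK1 fell by 0.32, of 13 (1 adjusted over the list alone), a call that ended without mock replicate 1, 2 or 3 or BA replicate 1, 2 or 4 (highest adjusted p = 0.121) and under 3 other alternatives. Limma called 0 members of the synthesis, auxin, jasmonate, abscisic acid, touch, low oxygen, heat shock, clock, nutrient uptake, secondary wall, cell cycle, stomatal lineage, root marker and reference lists. Adjusted over the list alone, 3 nutrient uptake genes, 1 heat shock gene, 1 type-B response regulator and 1 AHP gene were lower. Without mock replicate 3 the count of called genes was 811, without mock replicate 1 it was 977, in a fit of the compared groups alone 989 and in 1 fit of all 8 groups 2319, and with scaling by read totals the split was 949 higher and 321 lower.

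In ahp4 shoots (n = 3 each) ARR15 rose 16.3-fold, from 0.507 ± 0.634 to 22.4 ± 2.08 FPKM, ARR5 rose 9.85-fold, ARR7 6.90-fold and ARR4 5.22-fold. CRF2 rose 3.31-fold and RL4, of a family of small MYB-like proteins, 3.22-fold, and MIR864, at 0 in each mock library, had 5.43 ± 1.93 FPKM with BA. The small nucleolar RNA gene U60.2F rose 9.14-fold, but it lies in an intron of FIB2 and its reads cannot be told from that gene's. The carboxylesterase gene CXE20 fell from 5.89 ± 0.824 to 2.43 ± 0.0276 FPKM and the epoxide hydrolase gene SEH from 124 ± 21.9 to 62.2 ± 7.93 FPKM. Limma called 716 of 18246 genes, 534 higher and 182 lower, and 142 by a log2 change of 1 or more.

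All 8 type-A genes rose in ahp4 shoots (8 adjusted over the list alone; median 2.48, camera adjusted p = 4.55e-21), as did 3 of 6 breakdown genes (3 adjusted over the list alone; camera adjusted p = 9.39e-05) and 5 of 13 other textbook genes (9 adjusted over the list alone; camera adjusted p = 2.41e-11), each with an adjusted p = 0.00901 with an estimated correlation. AHK4 rose by 1.58 ± 0.14 and ERS1 fell by 0.47. The ARR6 call (5.93-fold) ended without BA replicate 3 (adjusted p = 0.0508) and the ERS1 call without BA replicate 2 (adjusted p = 0.054) and in a fit of the compared groups alone (adjusted p = 0.0546). The count was 330 without mock replicate 2, 353 without BA replicate 2, 367 without mock replicate 3 and 441 without BA replicate 3, and it was 1450 with array weights, 1287 in 1 fit of all 8 groups and 450 in a fit of the compared groups alone. With scaling by read totals 614 genes were higher and 97 lower.

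**Figure D3:**
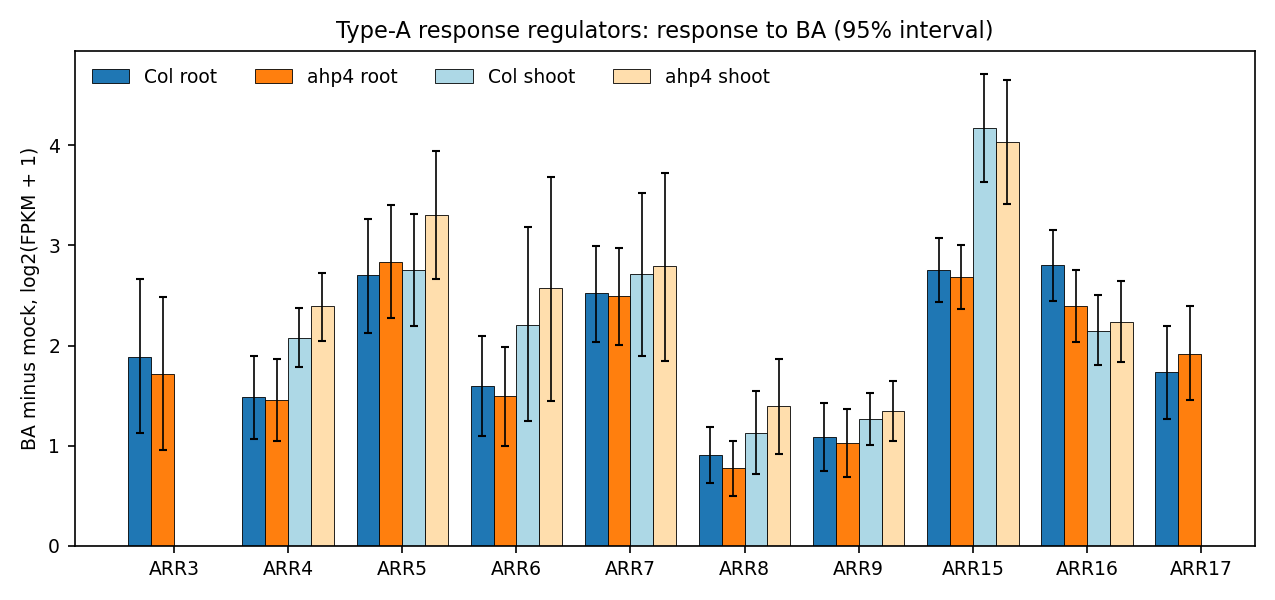
Change of each type-A response regulator with BA (BA minus mock, log2(FPKM + 1)) in Col and ahp4 roots and shoots; bars start at 0 and error bars are 95% intervals. The highest bar is ARR15 in Col shoots at 4.17, and ARR3 and ARR17 did not pass the filter in shoots.

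The response to BA was then compared between the genotypes. ARR5 rose by 2.70 ± 0.27 in Col roots and 2.83 ± 0.27 in ahp4 roots, ARR15 by 4.17 ± 0.25 in Col shoots and 4.03 ± 0.29 in ahp4 shoots, and CYP735A2 by 2.24 ± 0.15 and 2.44 ± 0.15 in the roots. Across the 5169 genes called in either root comparison the log2 changes correlated with a Pearson r of 0.941 and a Spearman rho of 0.919, and 98.1% had the same direction. Among these 1685 were called higher in both, 1146 lower in both and 2 in opposite directions, where independent lists would give 261, 157.5 and 405.9. Across the 1631 genes called in either shoot comparison r was 0.905 and rho 0.878, and 465 were higher in both, 107 lower in both and 0 opposite, where independent lists would give 28.1, 5.3 and 25. These correlations are across genes, which are not independent replicates, and the Col and ahp4 comparisons share no library. They do share 1 fit per organ and its spread for each gene, which favours calling the same genes in both. The counts for independent lists are therefore no strict reference.

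The test of the difference itself called no gene. Limma called 0 interactions between genotype and BA in roots (526 genes at an unadjusted p under 0.05, smallest adjusted p = 0.589) and 0 in shoots (336 genes, smallest adjusted p = 1), and voom called 0 in each. The mean change of the 10 type-A genes in roots was 1.95 in Col and 1.88 in ahp4, and of the 8 in shoots 2.31 and 2.51. The median 95% interval reached 0.388 to either side in roots and 0.469 in shoots. In simulated data a difference of 1 on the log2 scale was recovered for 59.7% of changed genes in roots (19139 genes tested) and 46.3% in shoots (17998 genes tested), and one of 0.5 for 19.4% and 3%, so differences of these sizes could be missed. Among the lists, the cytokinin synthesis list (median difference 0.18, camera adjusted p = 0.0332, adjusted p = 0.196 with an estimated correlation) and the touch list (0.27, camera adjusted p = 0.0142, adjusted p = 0.636 with an estimated correlation) passed in roots. In shoots the secondary wall list (0.24, camera adjusted p = 0.0189) and the cell cycle list (0.16, camera adjusted p = 0.0285) passed, each with an adjusted p = 0.831 with an estimated correlation. Neither passed with a term for 3 BA shoot libraries that stood apart from the others (adjusted p = 0.171 and adjusted p = 0.561). No member of these lists was called, over all genes or adjusted over the list alone. Without ahp4 root mock replicate 1, the library with conflicting labels, 7 lists passed in roots, tested at the preset correlation only. Without Col root BA replicate 1 limma called 1 interaction.

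**Figure D4:**
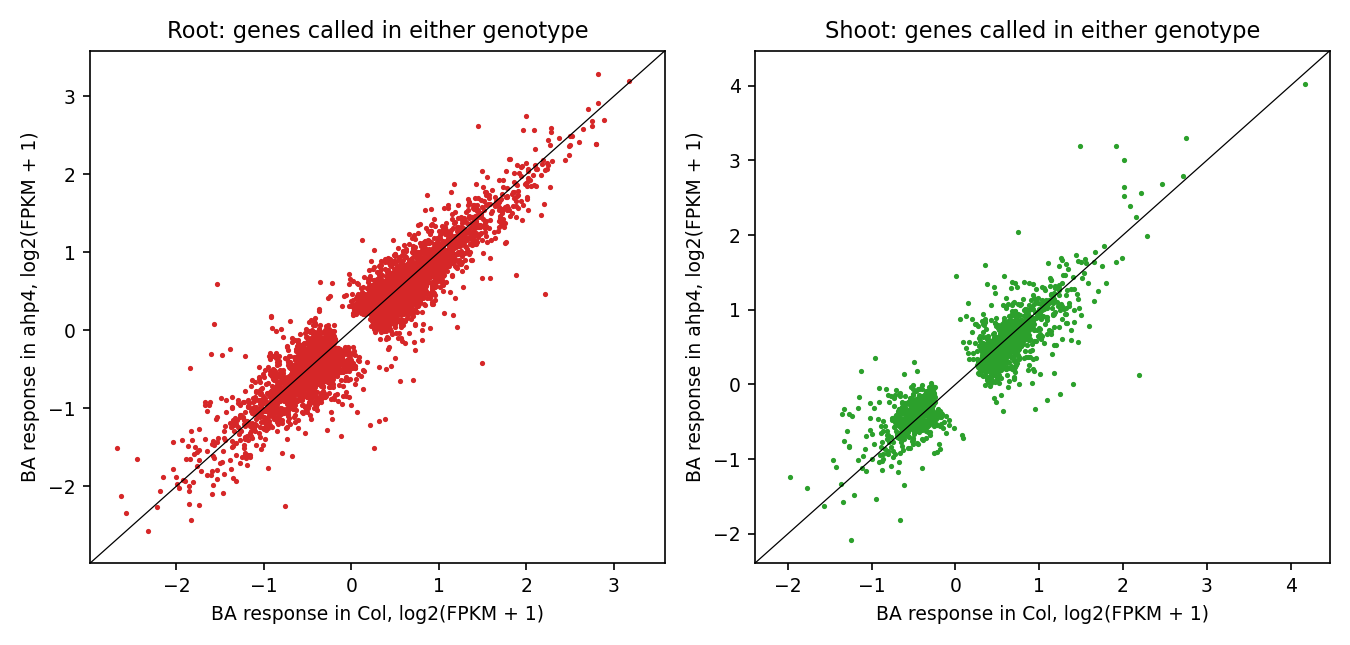
Log2 change with BA in ahp4 against that in Col for each gene called in either genotype, in roots (5169 genes, left) and shoots (1631 genes, right). Each point is a gene and the line marks equal changes; r across genes was 0.941 in roots and 0.905 in shoots.

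Few genes were called between ahp4 and Col in mock roots. CYP78A8, of a cytochrome P450 family, was 3.74-fold higher in ahp4 (11.9 ± 2.82 against 2.42 ± 0.413 FPKM, SD, n = 4 each), and UMAMIT17 3.24-fold (44.5 ± 9.24 against 13 ± 2.14 FPKM). SDH8, which encodes a subunit of mitochondrial complex II, was 2.16-fold higher, with reads that may be shared with the overlapping gene AT2G46380. UMAMIT10 was 2.21-fold higher and the sulfate transporter gene SULTR3;5 1.70-fold. The long noncoding RNA AT4G06835, chosen after its values were seen, was 7.63-fold higher (16.0 ± 1.63 against 1.27 ± 0.529 FPKM), and it overlaps AT4G03005, so its reads may be shared. AT5G35940, also chosen after its values were seen, was lower by 1.59 (10.5 ± 3.89 against 33.4 ± 10.7 FPKM).

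Limma called 17 of 19418 genes in mock roots, 15 higher and 2 lower. Each was without overlap between the libraries, but the genes were called on these same libraries, so this adds no support. The calls of CYP78A8, UMAMIT17, SDH8, AT5G35940 and AT4G06835 held without each library in turn, while the other 12 ended without at least 1, UMAMIT10 without ahp4 replicate 2, 3 or 4 or Col replicate 1 or 2 (highest adjusted p = 0.105) and under 2 other alternatives, and SULTR3;5 without any library but Col replicate 3 (highest adjusted p = 0.175) and under 7. The count was 5 without ahp4 replicate 4, 7 without ahp4 replicate 3, 8 without ahp4 replicate 2 or Col replicate 3 and 9 without Col replicate 1. With a pseudocount of 0.1 the call of AT4G06835 ended (adjusted p = 0.066), and in a fit of the compared groups alone that of AT5G35940 (adjusted p = 0.081). No list passed, and no member of a list was called over all genes. Of all genes 1754 (9.03%) had an unadjusted limma p under 0.05, above the share of 0.05 that no difference would give on average. More genes may therefore differ than were called. In simulated data a change of 0.5 on the log2 scale was recovered for 56.7% of changed genes. Adjusted over the list alone, 2 jasmonate genes, 2 abscisic acid genes, 1 heat shock gene and 1 nutrient uptake gene were higher, and 1 touch gene and 1 of the other textbook genes lower. In the camera test 7 lists passed without ahp4 root mock replicate 1, at the preset correlation only, as no estimated correlation was used without this library.

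In BA roots CYP78A8 was 2.51-fold higher in ahp4 (10.8 ± 1.82 against 3.71 ± 0.958 FPKM, n = 4 each) and UMAMIT17 2.13-fold (7.43 ± 1.74 against 2.95 ± 0.765 FPKM). AT4G06835 was 6.09-fold higher and AT5G35940 was lower by 1.43. These 4 genes and an unannotated model that was 2.36-fold higher (11 ± 1.65 against 4.09 ± 0.984 FPKM) made up the 5 genes that limma called of 19418. The last 3 named were chosen after their values were seen. The low oxygen list was higher by a median of 0.68 (camera adjusted p = 0.000703) and the heat shock list by 0.34 (camera adjusted p = 0.035), each with an adjusted p = 0.512 with an estimated correlation and with no member called over all genes. Adjusted over the list alone 1 heat shock gene, 1 jasmonate gene and 1 abscisic acid gene were higher, and no low oxygen gene. The call of UMAMIT17 ended without any library but Col replicate 1 and ahp4 replicate 4, and that of AT5G35940 without any but ahp4 replicate 1 (highest adjusted p = 0.189 for each). The count was 3 without Col replicate 2 or 3 or ahp4 replicate 2 or 3. Both calls also ended under 7 and 4 of the other alternatives, and those of AT4G06835 and the unannotated model ended with a pseudocount of 0.1 (adjusted p = 0.133 for each). In a fit of the compared groups alone the calls of AT4G06835 (adjusted p = 0.0629), CYP78A8 and the unannotated model (adjusted p = 0.0526 for each) ended.

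In shoots AT4G06835 was the 1 gene called between ahp4 and Col under either treatment. It had 25.3 ± 10.1 FPKM in ahp4 (n = 3) against 0.456 ± 0.374 in Col (n = 4) under mock, and 22.6 ± 1.63 against 0.332 ± 0.423 with BA. CYP78A8 stayed under the filter in shoots, with 0.540 ± 0.532 FPKM in ahp4 and 0.195 ± 0.148 in Col under mock. AHP1, AHP2, AHP3, AHP4 and AHP5 were not called over all genes, and adjusted over the list alone 1 AHP gene was lower under each treatment. In BA shoots the AHP list, which holds AHP4 itself, was lower by a median of 0.28 (camera adjusted p = 0.00478, adjusted p = 0.312 with an estimated correlation). The jasmonate list (camera adjusted p = 0.0176) was lower there, and the secondary wall (camera adjusted p = 0.039), cell cycle (camera adjusted p = 0.0291) and stomatal lineage lists (camera adjusted p = 0.0374) were higher, each with an adjusted p = 0.701 with an estimated correlation. In a fit without a genotype term, ahp4 replicates 2 and 3 and Col replicate 4 differed from the other 4 BA shoot libraries for 473 genes. This split was found after seeing the data and taken for its highest count of genes, so the list p-values for it are only descriptive. In these 3 the secondary wall list was higher by a median of 0.19 (camera adjusted p = 0.024) and the cell cycle list by 0.46 (camera adjusted p = 9.92e-05), each with an adjusted p = 0.318 with an estimated correlation. The stomatal lineage list was higher by 0.43 (camera adjusted p = 0.000604, adjusted p = 0.151 with an estimated correlation). The low oxygen list (1.34, camera adjusted p = 1.01e-06) and the auxin list (0.17, camera adjusted p = 0.0414) were higher in them too. The shoot markers (-0.3) and the reference genes (-0.36) were lower (camera adjusted p = 0.000697 for each). With an estimated correlation no list passed for this split (adjusted p of 0.151 or more). With a term for these libraries, tested at the preset correlation only, the jasmonate list passed (median -0.46, camera adjusted p = 0.000956). These libraries are spread unevenly over the genotypes, so the term overlaps in part with genotype. The AHP (adjusted p = 0.0651), secondary wall (adjusted p = 0.395), cell cycle and stomatal lineage lists (adjusted p = 0.788 for each) did not pass with the term. With a pseudocount of 0.1 the mock call of AT4G06835 ended (adjusted p = 0.0834).

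The response of Col roots to BA differed from that of Col shoots for many genes. GH3.3 changed by 3.62 ± 0.48 more in roots on the log2 scale, ACS7 by 3.29 ± 0.55 more and YLS9 by 2.62 ± 0.31 more. TPS13 (-2.66 ± 0.31), IPT5 (-2.05 ± 0.23) and IPT3 (-1.68 ± 0.25) had root minus shoot differences below 0. Among type-A genes ARR3 (1.76 ± 0.43) and ARR17 (1.63 ± 0.32) had differences above 0 and ARR15 (-1.42 ± 0.30) below 0. ARR3 had means of 0.0629 FPKM in mock shoots and 0.179 FPKM in BA shoots, and ARR17 of 0.233 and 0.301 FPKM. YLS9 had 0 and 0.525 FPKM there, TPS13 0 and 0.0173, IPT5 0.251 and 0.13, NRT2.1 0.189 and 0.381 and FIT 0.187 and 0.206, so on the log2(FPKM + 1) scale the shoot changes of these 7 genes stay small whatever their ratio. CYP735A2 (1.64 ± 0.40) and NCED3 (1.5 ± 0.29) had higher changes in roots, CRF2 (-1.5 ± 0.31) and UGT76C2 (-0.85 ± 0.17) higher changes in shoots, and NRT2.1 (-1.63 ± 0.37) and FIT (-1.63 ± 0.28) differences below 0. With a pseudocount of 0.1 the calls of YLS9, ARR3, ARR15, ARR17, CYP735A2, NRT2.1 and FIT ended (adjusted p from 0.0871 for FIT to 0.347 for CYP735A2), and with voom these and the calls of TPS13 and IPT5 ended (adjusted p from 0.0759 for TPS13 to 0.893 for YLS9). The YLS9 difference was 1.05 with that pseudocount and 0.42 with voom. That of ARR17 was 2.63 and 2.94, that of IPT3 -2.69 and -2.85 and that of NCED3 2.48 and 2.62. Limma called 2411 of 20818 genes, 1169 with a higher and 1242 with a lower value in roots, and voom called 1562. Across the 4331 genes called in either organ of Col r was 0.339 (rho 0.343) and 66.1% had the same direction, and across 3749 genes in ahp4 r was 0.287 (rho 0.278) and 63.2% had the same direction. The difference between ahp4 and Col under mock differed between organs for 1 gene, CYP78A8 (1.58 ± 0.26 more in roots, limma adjusted p = 0.035), and that call ended without any library but Col shoot replicate 2, Col root replicate 4, ahp4 root replicate 1 and ahp4 shoot replicate 2 (highest adjusted p = 0.309), with a pseudocount of 0.1 (adjusted p = 0.954) and with voom (adjusted p = 0.998).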

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

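The split tests at the end of this part were planned, while the tests on leaf transcripts, on a wrong label, on a difference between the mock samples and on neighbouring genes were chosen only after the results were seen.

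In 8 of 114 groups of 4 libraries, 1 value lay far from the other 3, by a gap past Dixon's 95% critical value, and chance gives this in about 1 of 20 groups. AHP4 had 0.514 FPKM in ahp4 root BA replicate 1, with the others at 0, and 3.71 FPKM in Col shoot BA replicate 3, with the others at 1.61 to 1.88. ARR5 had 203 FPKM in ahp4 root BA replicate 3 (others 166 to 170). In Col shoot mock replicate 2, ARR5 had 5.77 FPKM (others 2.33 to 2.76), ARR6 20.5 (others 4.59 to 6.55) and ARR7 42.8 (others 12.2 to 16.2). ARR16 had 2.16 FPKM in ahp4 root mock replicate 2 (others 1.14 to 1.29). ARR17 had 0.931 FPKM in Col shoot mock replicate 1, with the others at 0.

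By the test of the difference itself, the BA response of Col differed between roots and shoots for 2411 genes. Among type-A genes the root minus shoot difference was 1.76 for ARR3, 1.63 for ARR17 and -1.42 for ARR15, and these 3 calls ended with a pseudocount of 0.1 (1.59, 2.63 and -1.55) and with voom (1.69, 2.94 and -1.43). The difference between ahp4 and Col under mock was 1.58 higher in roots than in shoots for CYP78A8.

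LHCB2.1 and HEMA1, which are abundant in leaves, were higher with BA in roots, and shoot tissue carried into the root samples is a technical explanation for both. Carried tissue would bring LHCB2.1 and RBCS1A in the ratio of shoots, and their log2 ratio was -2.85 ± 0.40 in root mock and -2.77 ± 0.21 in shoot mock libraries. With BA it was higher in roots than in shoots by 0.98 in Col (two-sided exact permutation p = 0.0571) and by 1.28 in ahp4 (exact permutation p = 0.114). Over both genotypes it was -1.42 ± 0.92 in root BA and -2.55 ± 0.23 in shoot BA libraries (exact permutation p = 0.00668). That goes against carried tissue, but LHCB2.1 was picked by its rise in these same root libraries. The tests within a genotype do not exclude such tissue for LHCB2.1. For HEMA1 the largest share of shoot tissue that LHCB1.3 allows, 0.795%, would bring 11.3% of the rise. That was above the 10% set as the bound, so it stays open that such tissue may add a part of it. Over both genotypes HEMA1 rose from 27.2 ± 2.75 to 47.2 ± 4.91 FPKM in roots, and that share would bring 2.27 FPKM. By this measure the values argue against carried tissue as the cause of the whole HEMA1 rise. A response of root cells to BA stays open for LHCB2.1 and, for HEMA1, is left as an explanation of the rest of the rise.

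The genes called between ahp4 and Col in roots could come from a wrong label, from another difference between the mock samples, or from chromosome stretches that differ between the lines. Against the wrong label, ahp4 root mock replicate 1 had 21.4 FPKM of ARR5, where the 8 root BA libraries had 140 to 203, and 18 FPKM of AT4G06835, where the 8 Col root libraries had 0 to 2.57. Against a difference of the mock samples alone as the cause of all 17 genes called in mock roots, their mean difference in BA roots, signed as in mock roots, was 0.57 (two-sided exact permutation p = 0.0286, the smallest these libraries can give), but of the 13 not called there only 9 had the same sign (exact binomial p = 0.267), so it stays open for these. None of the called genes lay within 200 genes of AHP4 (0), a count that any random set reaches, so this cannot decide on a stretch around it. Of the 16 genes with a known place 2 lay within 50 genes of another, which is no more than chance gives (as many in a share of 0.322 of 10000 random sets). These 2, AT1G08903 and AT1G67148, were direct neighbours in the gene order, and both were higher in ahp4 mock roots (log2 1.01 and 0.78). So close a pair was not tested apart from the window of 50 genes. A stretch at this pair, longer stretches or ones with 1 called gene each are not excluded, and the genotype itself stays open.

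Other splits of the same libraries were used to ask whether chance in the grouping of these samples can be excluded. It can for the BA response of Col roots (1 of 35 splits called as many genes, 3982 against at most 137 in another), of ahp4 roots (1 of 35, 4020 against 174) and of Col shoots (1 of 35, 1487 against 13). Between ahp4 and Col no other split called as many genes in mock roots (1 of 35, 17 against 1) or BA roots (1 of 35, 5 against 1). A share of 1 of 35 is the smallest these splits can give, and the shares were not adjusted over the comparisons. The splits exchange samples that may be technical repeats, so they cannot exclude a chance difference between cultures. For ahp4 shoots 10 splits are too few for a share under 0.05, with 716 genes in the real split and 0 in the highest other. Chance cannot be excluded for a count of 1 gene in mock shoots (8 of 35 splits, highest other 2) and in BA shoots (6 of 35, highest other 473). This is about the count and not about AT4G06835, the gene called, which had 10.1 FPKM or more in each ahp4 library and 2.57 FPKM or less in each Col library of either organ. The split with 473 genes set ahp4 replicates 2 and 3 and Col replicate 4 against the other 4 BA shoot libraries, which points to a structure of these samples other than genotype. For the interactions 0 genes were called, a count that any split reaches, so that all 100 drawn splits gave as many (highest others 18 in roots and 28 in shoots) says nothing about chance. For the root minus shoot difference of the BA response in Col, 2 of 100 splits called as many genes (2411 in the real split). The other split, with 2557 genes, exchanged all root mock and BA labels and those of 1 mock and 1 BA shoot library. These splits exchanged mock and BA labels within an organ, which takes away the BA response itself. They therefore cannot decide whether chance explains a difference between the organs. Chance cannot be excluded for the count of the difference between ahp4 and Col by organ (19 of 100, 1 gene against 3).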

How the results depend on the processing

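Voom, scaling by read totals, the shoot marker covariate, the term for 3 BA shoot libraries and the scaling of AHP levels were chosen after seeing the data. Of 321 calls of named genes, 247 held without each library in turn. The cause was not tested for any change named here, except that fewer libraries lower the power of a test. Depth limits low genes such as AHP4, which had 6 to 174 rebuilt reads per group.

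In roots quantile normalization turned the majority of BA calls from higher to lower, with 2112 higher and 2218 lower in Col and 2088 and 2102 in ahp4. BA called 2319 genes in Col shoots in 1 fit of all 8 groups and 989 in a fit of the compared groups. In ahp4 shoots it called 1450 with array weights, 1287 in 1 fit of all 8 groups and 450 in a fit of the compared groups. With read totals 949 genes were higher and 321 lower in Col shoots, and 614 and 97 in ahp4 shoots. Between ahp4 and Col in mock roots, 10 genes were called with a pseudocount of 0.1, 10 with no filter, 26 with quantile normalization, 51 with array weights, 9 in a fit of the compared groups and 7 with voom. In BA roots these were 2 with a pseudocount of 0.1, 3 with no filter, 3 with quantile normalization, 3 with the replicate block and 1 in a fit of the compared groups. In mock shoots 0 were called with a pseudocount of 0.1 and 2 with no filter, and in BA shoots 2 with no filter. The root interaction had 1 gene in 1 fit of all 8 groups. The root minus shoot difference of the BA response had 1562 with voom. The difference between ahp4 and Col by organ had 0 with a pseudocount of 0.1 or voom and 2 with no filter, quantile normalization, array weights or read totals.

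With an estimated correlation 4 lists passed in Col roots with BA, 0 in ahp4 roots with BA, 0 between the genotypes in BA roots and in BA shoots, and 0 for the interactions. With the term for 3 BA shoot libraries 5 lists passed in ahp4 shoots with BA (auxin and low oxygen, both lower, were added), 1 between the genotypes in BA shoots (jasmonate) and 0 for the shoot interaction. An estimated correlation was not used with this term. With the replicate block 4 lists passed between the genotypes in mock roots (abscisic acid, heat shock, nutrient uptake and cell cycle), 5 in BA roots (low oxygen, heat shock, abscisic acid, iron deficiency and cell cycle) and 3 in BA shoots (AHP, cell cycle and stomatal lineage, not jasmonate or secondary wall). The block was tested at the preset correlation only. AHP2 was higher in roots by 0.212 with quantile normalization and 0.561 with read totals, and AHP5 turned to 0.391 with read totals. Over genes called in both comparisons r was 0.979 between genotypes in roots, 0.966 in shoots, 0.776 between organs in Col and 0.785 in ahp4, and with a pseudocount of 0.1 it was 0.923 and 0.855 between genotypes. The root minus shoot difference turned to -0.125 (pseudocount of 0.1) and -0.833 (voom) for CKX3 and to 0.432 (voom) for GATA22.

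Without 1 library at a time the counts ran from 3053 to 3786 in Col roots, 3178 to 4230 in ahp4 roots, 811 to 1439 in Col shoots and 330 to 659 in ahp4 shoots with BA. Between genotypes they ran from 5 to 15 in mock roots and 3 to 4 in BA roots, for the root interaction from 0 to 1, for the root minus shoot difference from 1818 to 2410 and for the genotype difference by organ from 0 to 1. Without ahp4 root mock replicate 1, 7 lists passed between genotypes in mock roots, 7 for the root interaction and 6 in ahp4 roots with BA. These were tested at the preset correlation only. The correlations ran from 0.924 to 0.944 and 0.867 to 0.927 between genotypes, and from 0.309 to 0.378 and 0.226 to 0.348 between organs.

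Replicate numbers were shared across groups, but same-numbered libraries deviated together in only some pairs (r from -0.111 to 0.359 in roots and -0.129 to 0.317 in shoots). In roots their median r was 0.05 (over 0.1 in 10 of 24 pairs), against -0.0245 for the 72 other pairs. In shoots it was 0.033 (5 of 19) against -0.009. The numbers were not taken to pair libraries, but a weak shared deviation is not excluded. Root and shoot libraries were not checked for pairing with each other. With the replicate block 4098, 4183, 1423 and 683 genes were called for BA in Col roots, ahp4 roots, Col shoots and ahp4 shoots, 23 and 3 between genotypes in mock and BA roots, 1 in mock and 1 in BA shoots, 0 for each interaction, 2536 for the root minus shoot difference and 1 by organ and genotype, which was not CYP78A8.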

Other observations

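All tests in this part were chosen only after the results were seen.

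Genes of ribosome biogenesis were higher with BA in shoots. FIB2, for the nucleolar methyltransferase fibrillarin, changed by 1.47 ± 0.11 on the log2 scale in Col shoots, the histone deacetylase gene HDT4 by 1.33 ± 0.14, RID2 by 0.97 ± 0.12 and NSN1, for a nucleolar GTP-binding protein, by 0.93 ± 0.09. These genes were chosen after their values were seen, from a list of 100 genes taken from annotation text after the Col shoot result. Of 79 tested, 41 were called higher and none lower in Col shoots (median 0.56), and in ahp4 shoots, which share no library with these, 33 were called higher and none lower (median 0.51, camera p = 0.000806 with an estimated correlation). The hypothesis that BA may raise these transcripts in shoots passed this test. In Col roots the median was 0.01, and -0.05 with quantile normalization, with 6 higher and 1 lower of 77, so a rise in roots was not seen in the list as a whole and is left open for single members.

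A lower response of type-A genes in ahp4 was tested as a hypothesis: the loss of AHP4 could lower their mean BA response by 25% or more. In roots the difference of responses was -0.07, with a 95% interval from -0.65 to 0.51, against 0.49 for that part of the Col response, so this stays open. In shoots it was 0.20, with an interval from -0.57 to 0.96, against 0.58, which argues against it by a margin of only 0.01.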
